A study of Mus musculus with 6 samples.

How the data were processed

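Liver RNA was sequenced from 6 C57BL/6 mice that had been fed a 60% high-fat diet for 8 weeks: 3 wild type mice and 3 mice with a hepatocyte knockout of the microRNAs let-7b and let-7c-2 (LKO). The labels name the groups and number the mice 1 to 3 within each. They give the tissue as liver, so each library holds all liver cell types. Libraries came from a stranded mRNA preparation, per the labels' protocols. That preparation selects polyadenylated RNA, so mature microRNAs were not measured.

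The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.36, STAR 2.5.1, Picard 1.84, RSEM 1.2.22 and edgeR, with genome build mm10 and with no role or order for any tool. The version of the last of these, the annotation, the strand setting and any filter on genes are not given in the sources used here. The authors deposited 1 table per mouse with 14002 genes and 1 expression signal per gene. The unit of this signal is not named in the file headers. From the values, every positive signal was a multiple of a hundredth of a library-specific step, within 0.05 of a hundredth, so the deposited signal behaves as an estimated count with 2 decimals times 1 factor per library. Between 82.0% and 83.1% of the positive values came out as whole reads within 0.005 of a read. This share was too low to treat the values as whole read counts, so count models were not run. Dividing each value by its library's step gave estimated counts of 8549483, 9432187 and 10398390 in wild type replicates 1, 2 and 3. The LKO replicates 1, 2 and 3 held 8636681, 8637204 and 10764825. These totals cover the listed genes. A signal of 3 reads corresponded to between 0.331 and 0.447 units, and intervals or floors built from reads cover counting error only. Ratios and bounds built from reads were scaled by the library steps.

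Of the 14002 gene identifiers, 13977 were found in GENCODE M21 (GRCm38, the same assembly as mm10), which supplied coordinates, biotypes and 3′ untranslated regions. In 22 rows the name was missing, and in 18 rows a spreadsheet had turned it into a date. GENCODE M21 names were used by identifier for 25 of these rows. The 757 genes at 0 in all 6 libraries were left out.

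The design written before the data were examined assumed counts or RSEM expected counts and a quasi-likelihood count model, with a fallback for normalized values. The unit of the deposited signal called for the fallback, which is the test reported. Genes with a mean value of at least 1 were kept, log2(value + 1) was fitted with limma 3.58.1 in R 4.3.3 using empirical Bayes moderation with a mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method. Genes with an adjusted p under 0.05 are called raised or lowered in LKO. Log2 fold changes are LKO minus wild type on the log2(value + 1) scale, which understates changes of low genes. The test was two-sided and used no block.

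Gene lists and cell type markers were fixed before the data were examined. Lists with at least 5 tested genes were tested with camera, a competitive test in limma, using a preset inter-gene correlation of 0.01. This made 24 tests, of 23 lists and of all PPARα target lists joined, adjusted together. Marker lists were adjusted as a family of their own. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were alternatives. The let-7 seed test compared genes whose longest annotated 3′ untranslated region holds the 8mer CTACCTCA with genes that hold neither this site nor the 7mers CTACCTC and TACCTCA.

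Genes named in the text followed a rule fixed before the data were examined. It took Ppara, Rxra, Rnf8 and the listed neighbours of the let-7 locus. It added the 10 largest changes in each direction among called genes with an average log2 value of at least 1 and no overlap between the groups. From each list it took up to 4 called members with the smallest p, or the 2 most highly expressed members where none was called. It also took the 2 most highly expressed members of each marker list. Predicted genes are given only as a number. Genes named outside this rule are said to be so. Some genes that the rule takes are not reported here by name and are counted only.

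The scripts were tested on 20 simulated data sets with 200 changed genes each, taken from genes with a mean value of at least 5 and drawn with negative binomial noise from the real means, spreads and library sizes of the LKO and wild type comparison, with a mean of 11070 genes tested. At a fold of 1.5, 19.3% of the changed genes were recovered, and at 2, 4 and 8 the shares were 69.6%, 96.4% and 98.1%. Of all calls, 5.69% were false. With no gene changed, the highest number of calls was 1. For the let-7 seed test, a simulated rise of 0.1 on the log2 scale was called in 20 of 20 data sets and a rise of 0.05 in 10 of 20, with genes drawn independently.

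Alternatives were median-of-ratios (RLE) factors, library size alone, no filter, a stricter filter (a value of at least 1 in at least 3 libraries), limma-voom on the estimated counts, a pseudocount of 0.1, the replicate number as a block, and leaving out each library in turn. Figures and genome scans used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.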

Results

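The series addresses a network of the nuclear receptor PPARα and let-7 microRNAs in hepatic lipid metabolism, as its title states. Livers of 3 wild type and 3 LKO mice were compared, all on the high-fat diet. PPARα is a fatty-acid-activated transcription factor that drives fatty acid oxidation genes in hepatocytes. The let-7 family represses messenger RNAs through short sites in their 3′ untranslated regions. Estimated counts ranged from 8549483 to 10764825 per library. No pair of libraries agreed within counting noise, so all 6 were kept as separate samples. The p-values of the limma gene tests rest on the spread between these 6 samples. Those of camera with the preset correlation compare a list's genes with the other genes, and do not measure that spread for the list.

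The knocked-out microRNAs themselves, let-7b (chromosome 15, 85707319 to 85707403, GRCm38) and let-7c-2 (85706603 to 85706697), and their host transcript were not analysed here, so the knockout was not checked at its own transcripts. The first principal component held 47.1% of the variance of the log2 values and separated the groups. Libraries of the same group correlated across genes at r = 0.977 to 0.985, and libraries of different groups at r = 0.958 to 0.975. LKO replicate 2 stood apart in composition, with 24.2% of its signal in its 10 most abundant genes against 18.7% to 21.02% in the other 5 libraries.

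The comparison of LKO with wild type livers asked which transcripts differ when hepatocyte let-7b and let-7c-2 are removed under the high-fat diet. Of 11168 genes tested with limma, 203 were raised and 189 were lowered in LKO. Of these 392 genes, 211 changed more than 2-fold. At an unadjusted p under 0.05 the counts were 1070 and 989. In 24.2% of all tested genes the 3 LKO values did not overlap the 3 wild type values, where chance gives 10%. The count of raised genes moved by over 1.5 times when any library but LKO replicate 1 was left out. The counts were 120 raised and 138 lowered without wild type replicate 1, 88 and 79 without replicate 2, and 114 and 105 without replicate 3. Without LKO replicate 2 they were 92 and 107, and without LKO replicate 3 they were 76 and 97. Of the 63 called genes named by the rule or beside the let-7 locus, 33 kept their call with each library left out in turn. None of the 63 changed sign. Leaving out a library could not change it, as the groups overlapped in none of the 392 called genes.

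Among the 10 largest rises, Moxd1, a monooxygenase-like gene, went from 1 read over the 3 wild type libraries to a mean value of 118 ± 22.5 (SD, n = 3) in LKO. The ratio of reads, scaled by the library steps, was 2918, with a 95% counting interval of 523 to 115300. The trefoil factor gene Tff3 had 2 wild type reads and a mean of 69.3 ± 53.0 in LKO, a ratio of 819 with an interval of 226 to 6768. Selenbp2, a selenium-binding protein gene, rose from 73.3 ± 11.5 to 1293 ± 538, a log2 fold change of 4.04 (SE 0.28). Its adjusted p in limma was 1.5e-04. The others named were Lnx1 (log2 fold change 3.06, or 5.59 with limma-voom), the major urinary protein genes Mup1 (3.01) and Mup7 (2.63), the chemokine gene Cxcl14 (2.95), the metallothionein gene Mt2 (2.88) and the fatty acid binding protein gene Fabp5 (2.68). The remaining 1 was a predicted gene. Mup genes are near-identical copies, so the split of reads between them is uncertain. The calls of Cxcl14, Mt2 and Mup7 were lost when some libraries were left out, with log2 fold changes of 2.23 to 3.52, 2.33 to 3.47 and 2.13 to 3.29 over the 6 fits.

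The 10 largest falls were led by Cyp2b9, a cytochrome P450 gene. It averaged 168 ± 21.6 in wild type and 0.363 ± 0.400 in LKO, a log2 fold change of -6.99 (SE 0.21, adjusted p in limma 1.7e-07). The fatty acid omega-hydroxylase genes Cyp4a14 and Cyp4a10 had log2 fold changes of -6.22 (SE 0.46) and -3.39 (SE 0.42). The acyl-CoA thioesterase genes Acot3, Acot1 and Acot2 had -4.90, -3.27 and -2.70. The lipid droplet genes Cidec and G0s2 had -2.87 and -2.68. The fatty acid transporter gene Cd36 had -2.86, and the semaphorin gene Sema5b had -2.79. Cyp2b, Cyp4a and Acot genes also belong to families of close copies, and their individual values are uncertain to that extent. G0s2 lost its call without any 1 library but LKO replicate 1. Its log2 fold change was -3.59 in that fit, which kept the call, and -2.08 without LKO replicate 3. Cidec lost its call without wild type replicate 2, at -2.66.

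PPARα target genes fell as a group, while the transcript of the receptor did not pass the test. For the group the camera adjusted p was 4.6e-23 with the preset correlation, and the adjusted p = 0.167 with an estimated correlation of 0.275. Ppara averaged 117 ± 9.93 in wild type and 119 ± 14.7 in LKO, a log2 fold change of 0.03 (SE 0.12, adjusted p in limma 0.93). Its partner Rxra averaged 546 ± 28.9 and 549 ± 30.9, a log2 fold change of 0.01 (SE 0.11, adjusted p 0.98). Of 72 tested PPARα targets, 29 fell, 1 rose and 42 did not pass. Adjusted over the list alone, 50 fell and 3 rose. The median log2 fold change was -0.62, and 66 of 72 values were negative. In the same livers the 12 mitochondrially encoded transcripts had a median of -0.33, with all 12 values negative. The gene that rose was the lipoprotein lipase gene Lpl (log2 fold change 1.44), named after its value was seen.

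Within the PPARα targets, peroxisomal and microsomal genes had the lowest median of the 4 groups, -1.03 over 19 genes. In this list 9 fell, none rose and, adjusted over the list alone, 15 fell. Besides the Cyp4a and Acot3 genes, Acot4 went from 46.4 ± 10.8 to 10.3 ± 4.97 (log2 fold change -2.14). Of 22 mitochondrial beta-oxidation genes 9 fell and none rose, with a median of -0.52, and adjusted over the list alone 18 fell. The medium-chain acyl-CoA dehydrogenase gene Acadm went from 523 ± 52.4 to 264 ± 31.8 (log2 fold change -0.99, SE 0.13). Hadh, which encodes the next dehydrogenase of the pathway for short chains, went from 565 ± 45.0 to 331 ± 32.7. Of 9 ketogenesis and fasting hormone genes 4 fell (6 adjusted over the list alone), with a median of -0.59. Those that fell included the pantetheinase gene Vnn1 (-2.29), the ketogenic gene Acat1 (-0.92) and the fasting hormone gene Fgf21 (-1.05). Of 22 lipid uptake and droplet genes 7 fell and 1 rose (11 and 3 adjusted over the list alone), with a median of -0.50. They included Plin2, which coats lipid droplets (-1.50), and the acyl-CoA synthetase gene Acsl1 (-1.15). The calls of Acat1, Fgf21, Plin2 and Acsl1 were lost when some libraries were left out. Over all 6 such fits, kept calls included, log2 fold changes ranged from -1.15 to -0.77 for Acat1 and -1.79 to -1.27 for Plin2. The adjusted p of Fgf21 and Acsl1 in limma reached 0.116 and 0.103. With an estimated correlation the adjusted p of these 4 lists was 0.102, 0.189, 0.182 and 0.189, in the same order. Kupffer cell and macrophage markers were higher in the same LKO livers, with a median of 0.81, hepatocyte markers had a median of 0.39 and mitochondrially encoded transcripts one of -0.33.

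**Figure D1:**
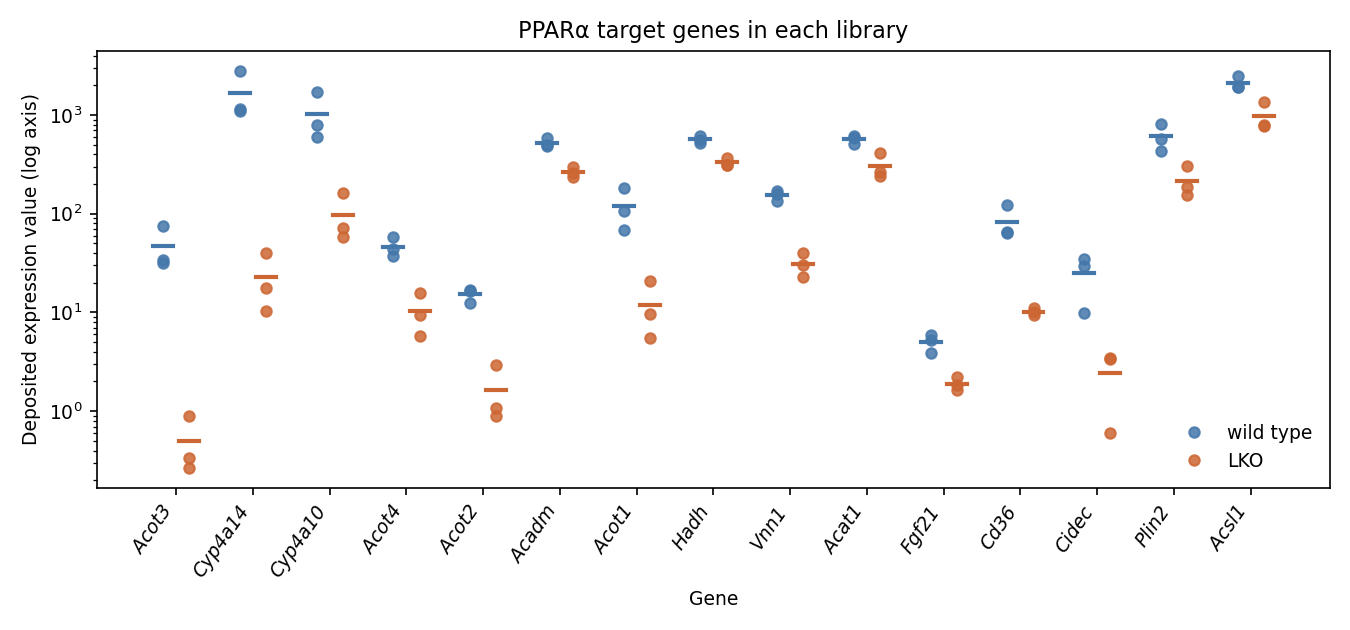
Deposited expression value (log axis) of 15 called PPARα target genes in each of the 6 libraries, with wild type in blue and LKO in orange; each point is a library and each bar the mean of 3. All 3 LKO points lie below all 3 wild type points in each gene, as for Cyp4a14 with means of 1687 and 22.6.

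Among the other lipid and drug metabolism lists, drug-metabolizing enzymes were called down and cholesterol genes up with the preset correlation, but neither with an estimated correlation (adjusted p = 0.167 and 0.651). In these livers Kupffer cell and macrophage markers had a median of 0.81 and mitochondrially encoded transcripts one of -0.33. Of 25 lipogenesis and triglyceride synthesis genes, the acylglycerol transferase gene Mogat1 (-1.82, or -2.95 with limma-voom) and the elongase gene Elovl5 (-0.85) fell and the acetyl-CoA carboxylase gene Acaca (1.32) rose. Adjusted over the list alone, 6 rose and 3 fell, and the list was not called (adjusted p 0.324 by camera) except without wild type replicate 2 (median 0.52, adjusted p 0.0069). Of 24 cholesterol genes none was called, and none adjusted over the list alone. Sc5d, among its most highly expressed members, had a log2 fold change of 0.09. The list itself was called up (median 0.28, adjusted p 0.041 by camera), with an adjusted p = 0.651 under an estimated correlation. Without wild type replicate 1 or 3 or LKO replicate 3 its adjusted p was 0.445, 0.276 and 0.145, and its median ran from 0.10 without wild type replicate 1 and 0.18 without replicate 3 to 0.46 without replicate 2. With a pseudocount of 0.1 its adjusted p was 0.0534. Of 21 bile acid genes, the hydroxylase gene Cyp7b1 (1.37) and the uptake transporter gene Slco1a1 (0.65) rose, both also male-biased list members. The export pump gene Abcc3 (-2.07) fell. Adjusted over the bile acid list alone, 4 rose and 1 fell. The bile acid list had a camera adjusted p of 0.0939, or 0.047 without wild type replicate 2 and 0.0244 without LKO replicate 1. Of 30 drug-metabolizing enzyme genes 5 fell and 1 rose (12 and 3 adjusted over the list alone), with a median of -0.30 and a camera adjusted p of 9.6e-04. Its adjusted p = 0.167 with an estimated correlation. Cyp3a11, a major drug-oxidizing enzyme, went from 1029 ± 392 to 233 ± 123 (log2 fold change -2.20), and Gsta2 had -1.74. Gstp1 (1.12), named after its value was seen, was the member that rose. Cyp2b13 had 138 reads in wild type and 1 in LKO, a ratio of 130 after scaling by the library steps, with a counting interval of 23.0 to 5182. Of 22 apolipoprotein and VLDL genes 3 rose (Apom 1.21, Scarb1 0.56, Abca1 0.55) and 2 fell, Apoc2 (-0.53) and, named after its value was seen, Apoa4, from 713 ± 276 to 322 ± 67.1. Adjusted over the list alone, 4 rose and 4 fell, and the list's adjusted p was 0.488. Of 25 glucose metabolism genes 1 rose, the binding protein gene Igfbp2 (0.97), and 1 fell. Adjusted over the list alone, 3 rose and 1 fell, and the list had an adjusted p of 0.13. In these lists Acaca, Elovl5, Abcc3, Slco1a1, Scarb1, Abca1 and Apoc2 lost their call in at least 1 fit with a library left out. Each kept its sign, as genes without overlap between the groups must.

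Whether let-7 targets rose was asked with a list of known targets and with sites in 3′ untranslated regions. Of 72 tested conserved let-7 targets 2 rose, none fell and 70 did not pass, and adjusted over the list alone 5 rose. Hmga1, a chromatin protein gene, went from 18.5 ± 1.08 to 30.4 ± 5.01 (log2 fold change 0.68). Ccnd1, which encodes cyclin D1, went from 13.5 ± 5.13 to 35.4 ± 13.9 (1.32). Hmga1 kept its call only without LKO replicate 1 and Ccnd1 only without wild type replicate 1, with log2 fold changes of 0.56 to 0.76 and 1.03 to 1.57 over the 6 fits. The median of the list was 0.17, or 0.11 with library size as the scaling, and 53 of 72 values were positive. The camera adjusted p was 5.2e-04 with the preset correlation, and the adjusted p = 0.167 with an estimated correlation of 0.0232. The median of Kupffer cell and macrophage markers, at 0.81, was higher in the same livers. The 394 tested genes with a let-7 8mer had a median log2 fold change 0.05 above that of 8862 genes with no site, with a camera p of 0.197. Of these 394 genes 6 rose and 7 fell. Against all genes without the 8mer, those with a 7mer site included, the median difference was 0.047. Among 12525 other 8mers found in a similar number of genes, 93.8% gave a smaller difference of that kind. Rnf8, a ubiquitin ligase gene, averaged 12.7 ± 3.29 in wild type and 14.2 ± 1.44 in LKO, a log2 fold change of 0.18 (SE 0.19, adjusted p in limma 0.673). Of 10 tested let-7 host and processing genes 0 were called in limma, and 0 adjusted over the list alone. Huwe1 had 0.15 and Dicer1 0.41, and the list had an adjusted p of 0.0905, or 0.0485 without wild type replicate 1.

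On chromosome 15, genes beside the let-7 locus were raised, in livers whose Kupffer cell and macrophage markers had a median of 0.81. Ppara starts 27.6 kb downstream of let-7b, and the raised genes lie beyond it. Of the 10 tested genes of the fixed list of the locus and its neighbours, 7 rose, and adjusted over the list alone 7 rose. The median was 0.97, with a camera adjusted p of 1.2e-07 and an adjusted p = 0.102 under an estimated correlation. Cdpf1 (85806972 to 85811697) averaged 1.98 ± 0.854 in wild type and 16.7 ± 1.08 in LKO, a log2 fold change of 2.61 (SE 0.22, adjusted p in limma 4.4e-04). Ttc38 (85832306 to 85858822) went from 111 ± 20.6 to 567 ± 105, a log2 fold change of 2.35 (SE 0.17). Gtse1 had 2.18 (SE 0.37, or 3.84 with limma-voom, where its adjusted p was 0.0549), Trmu 0.96 (SE 0.17), Celsr1 1.14 (SE 0.26), Gramd4 0.88 (SE 0.19) and Cerk 0.98 (SE 0.21). Tbc1d22a, which follows them and was named after its value was seen, had 1.15 (SE 0.13). On the other side of the locus, Atxn10 had -0.05 (SE 0.13) and Nup50 had 0.04 (SE 0.12). The other 2 tested genes within the same reach on that side, named after their values were seen, were not called in limma. 5031439G07Rik had -0.41 (SE 0.11, adjusted p 0.0814) with no overlap between the groups, and Fam118a had 0.54 (SE 0.28, adjusted p 0.332). The 8 raised genes are consecutive among the tested genes over 692 kb. Of the 8, 5 were called with limma-voom, and 6 with library size as the scaling, without the filter on low values or with a pseudocount of 0.1. The number called fell to between 3 and 6 when a library was left out (3 without LKO replicate 3, 4 without wild type replicate 1 or 2). All 8 log2 fold changes were positive in each of those fits. With a library left out this was fixed beforehand, as the groups did not overlap in any of the 8 genes.

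**Figure D2:**
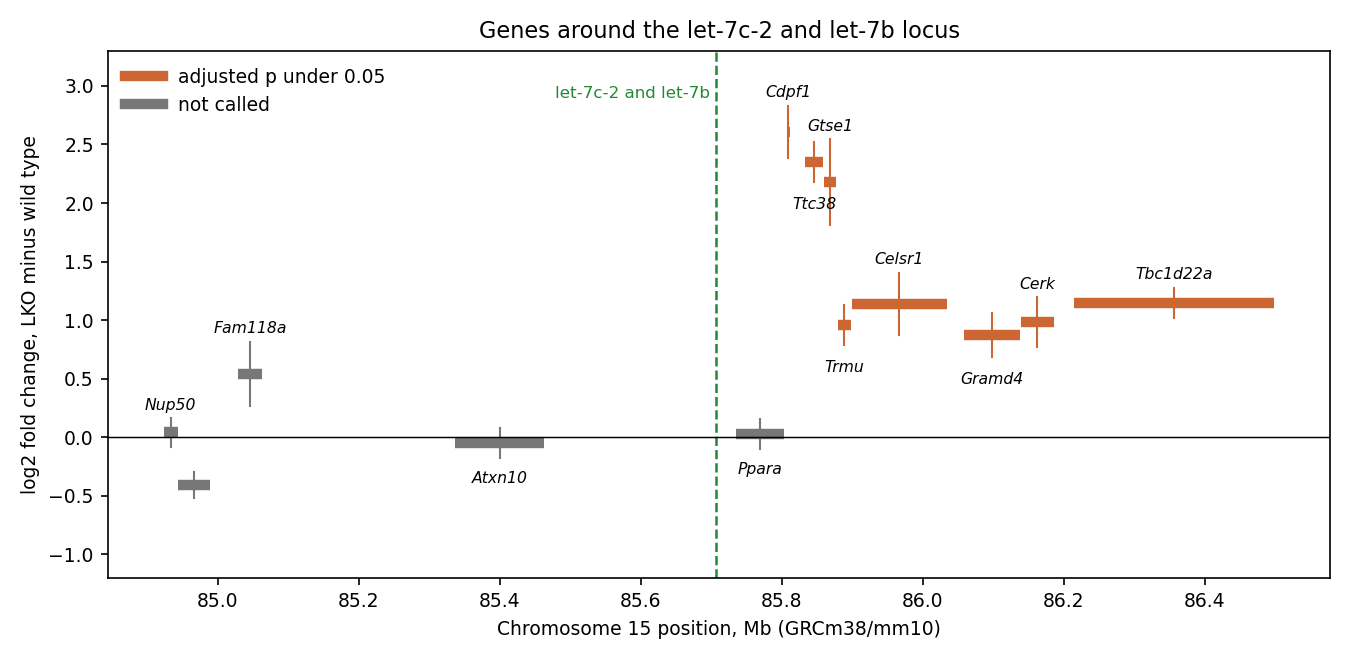
Log2 fold change (LKO minus wild type) of the tested genes against position on chromosome 15 in Mb (GRCm38); each bar spans a gene, vertical lines are the SE, orange marks adjusted p under 0.05, and the dashed line marks let-7c-2 and let-7b. The 8 genes from Cdpf1 to Tbc1d22a lie between 0.88 and 2.61, while Ppara lies at 0.03.

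Genes known to differ between male and female mouse liver moved in opposite directions, with both lists called at the preset correlation and neither at an estimated correlation (adjusted p = 0.172 for male-biased and 0.103 for female-biased genes). In the same livers Kupffer cell and macrophage markers had a median of 0.81 and mitochondrially encoded transcripts one of -0.33. Of 20 tested male-biased genes 10 rose and none fell, and adjusted over the list alone 12 rose. The median was 0.88, with a camera adjusted p of 3.3e-09 and an adjusted p = 0.172 under an estimated correlation. Besides Selenbp2 and Mup1, the complement gene C6 went from 151 ± 16.8 to 426 ± 52.9 (log2 fold change 1.49) and Susd4 from 26.3 ± 1.26 to 64.7 ± 11.9 (1.25). Of 9 tested female-biased genes 6 fell and none rose, and adjusted over the list alone 6 fell. The median was -2.47, with a camera adjusted p of 4.5e-09 and an adjusted p = 0.103 under an estimated correlation. Over the 13 members listed without the filter on low values the median was -0.24, with an adjusted p of 6.2e-07. With the few-read genes at their bounds the median of the 9 was -2.49. Hao2 had 112 reads in wild type and none in LKO, so it was at least 35.2-fold higher in wild type, from 3 reads over the group. Cyp2a4 went from 9.68 ± 5.32 to 0.780 ± 0.294. Cyp2b9, Cyp2b13 and Acot3 stand in this list as well as in those above. All 6 libraries expressed the Y-linked genes Ddx3y, with values of 29.9 to 40.8, and Eif2s3y, with 28.5 to 45.6, while Xist was listed at 0 in each. Of 4 tested sex chromosome genes none was called.

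**Figure D3:**
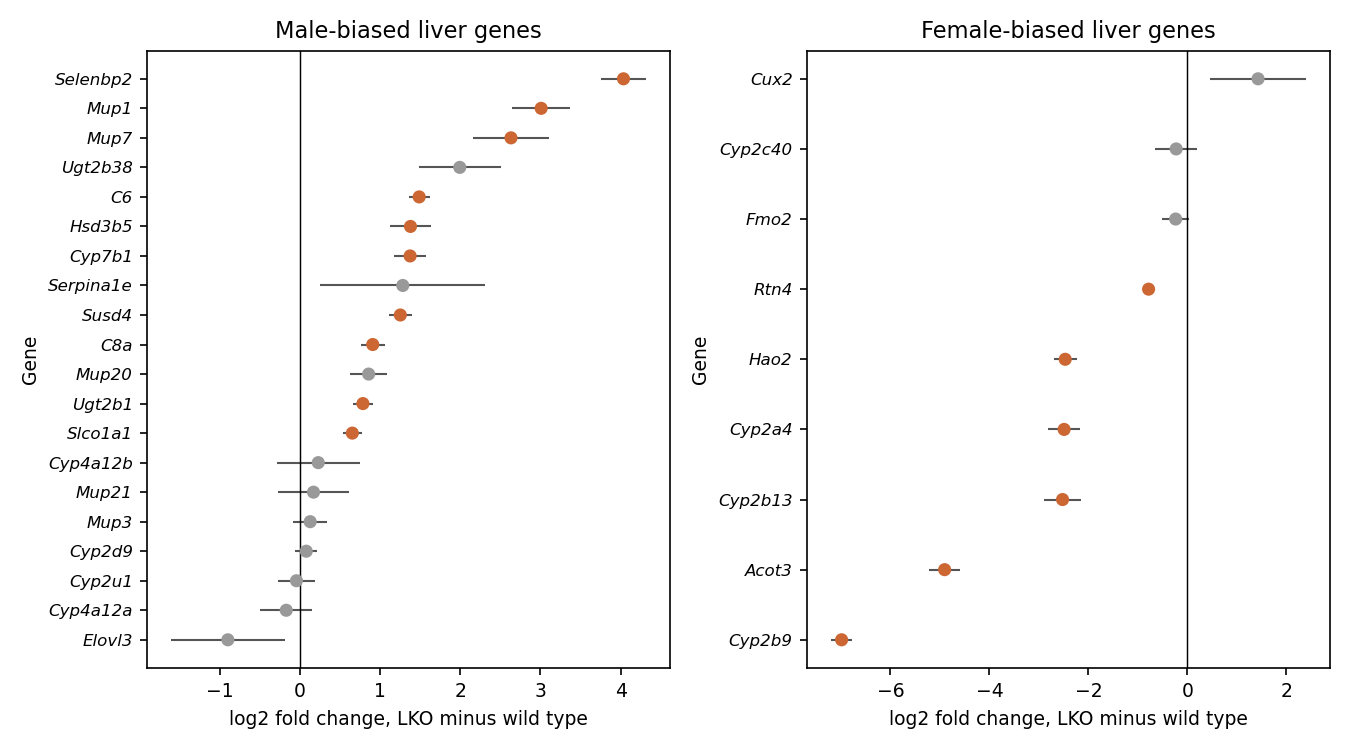
Log2 fold change (LKO minus wild type) of the 20 tested male-biased genes on the left and the 9 tested female-biased genes on the right; lines are the SE and orange marks adjusted p under 0.05. The male-biased genes reach 4.04 at Selenbp2, and the female-biased genes reach -6.99 at Cyp2b9.

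Of the immune and stress lists, interferon-stimulated genes were called down and acute phase and extracellular matrix genes up with the preset correlation. None of these lists was called with an estimated correlation (adjusted p = 0.224, 0.345 and 0.189) or by fry (0.081, 0.204 and 0.0509). The Kupffer cell and macrophage markers of the same livers had a median of 0.81 and mitochondrially encoded transcripts one of -0.33. Of 25 interferon-stimulated genes Ifit3 (-1.01) and Ifit1 (-1.14) fell, and adjusted over the list alone 4 fell. The list had a median of -0.30 and an adjusted p of 0.0013, with adjusted p = 0.224 under an estimated correlation. Without LKO replicate 3 the median was -0.14, with an adjusted p of 0.0112. Of 20 acute phase genes, which the liver secretes in inflammation, Orm1 rose from 320 ± 62.3 to 984 ± 477, and adjusted over the list alone 2 rose. The median was 0.62, with an adjusted p of 4.1e-05 and an adjusted p = 0.345 under an estimated correlation. Without LKO replicate 2 the median was 0.34, with an adjusted p of 0.0063 and with Orm1 no longer called (1.16), and without LKO replicate 1 it was 0.93. Of 20 extracellular matrix genes the collagen gene Col4a2 rose (0.84), and adjusted over the list alone 4 rose. The median was 0.29, with an adjusted p of 1.4e-04 and an adjusted p = 0.189 under an estimated correlation. It was 0.20 without wild type replicate 2, 0.49 without wild type replicate 1 and 0.48 without LKO replicate 3. The lists of inflammatory cytokines (Nfkbia -0.26, Spp1 1.02), nuclear receptors (Hnf4a 0.27), ER stress (Herpud1 -0.17, Hspa5 -0.37), cell cycle (Ccnd1 the 1 called gene) and circadian clock genes (Tef 0.31, Bhlhe40 0.59) were not called. Their adjusted p was 0.0598, 0.469, 0.393, 0.922 and 0.187. Adjusted over the list alone, 1 cytokine gene rose, 2 nuclear receptor genes rose and 4 fell, 2 cell cycle genes rose and 1 fell, and none of the others passed. The cytokine list had an adjusted p of 0.0386 without wild type replicate 2, 0.028 with library size as the scaling and 0.0157 by fry. The cell cycle list had a median of -0.0085 while its mean was 0.044. Ifit1 and Orm1 kept their call only without LKO replicate 1, and Col4a2 lost its call without wild type replicate 2 (0.80).

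Markers of cell types were compared in the same way. Of 12 Kupffer cell and macrophage markers 5 rose and none fell (11 adjusted over the list alone), and all 12 values were positive. Besides Clec4f, those that rose were Timd4, Vsig4, Csf1r and C1qc, named after their values were seen. Clec4f went from 29.6 ± 3.59 to 53.7 ± 9.74 (0.83, SE 0.16), and Cd5l had 0.61 (SE 0.15). Clec4f lost its call without wild type replicate 1 or 2 or LKO replicate 2 or 3 (range 0.73 to 0.99). The median was 0.81, with an adjusted p of 1.1e-09 and an adjusted p = 0.161 under an estimated correlation. Of 11 endothelial markers none was called, nor adjusted over the list alone (median 0.35, adjusted p 0.0019, and adjusted p = 0.161 under an estimated correlation). Eng had 0.16 and Clec4g 0.39. Stellate cell markers had a median of 0.057, a mean of -0.019 and an adjusted p of 0.928, with Ecm1 at -0.16 and Dcn at 0.04. The 10 hepatocyte markers had a median of 0.39 and an adjusted p of 0.0171, or 0.0545 without wild type replicate 3, with Alb at 0.03 and Apoa1 at 0.53. With an estimated correlation the hepatocyte list had an adjusted p = 0.161. Periportal markers (Pck1 0.29, Cps1 0.68) and pericentral markers (Cyp2e1 -0.18, Glul 0.23) had medians of 0.29 and 0.43, with adjusted p of 0.0163 and 0.0023, and an adjusted p = 0.161 for both with an estimated correlation. Without wild type replicate 3 the periportal list had a median of 0.16 and an adjusted p of 0.0504, and without LKO replicate 3 a median of 0.18. The erythroid markers, led by Hbb-bs (0.54) and Hba-a2 (0.64), had a median of 0.51 and an adjusted p of 0.0125, or 0.0502 without wild type replicate 2. It had an adjusted p = 0.258 with an estimated correlation, and 0.103 by fry. Hba-a1 and, among pericentral markers, Gulo were the members that rose in these lists, both named after their values were seen. In tests adjusted over the list alone, 2 hepatocyte, 4 periportal, 7 pericentral and 4 erythroid markers rose and 1 periportal marker fell. The 12 mitochondrially encoded transcripts, led by mt-Co1 and mt-Cytb (both -0.31), had a median of -0.33 and an adjusted p of 0.0025, with an adjusted p = 0.358 under an estimated correlation and 0.202 by fry. Immediate early genes (Dusp1 0.32, Hsph1 -0.40) had an adjusted p of 0.0978, or 0.0364 and 0.0273 without wild type replicate 2 and LKO replicate 2. Too few tested genes were left to test the lists for other cell types. The T cell marker Cd4 rose (1.43), a call lost without wild type replicate 2 (1.19) and LKO replicate 3 (1.44). Among 3 tested adipocyte markers Cidec fell and Lpl rose, while Fabp4 had -0.21. The tested B cell (Ighm 0.39, Igkc 0.93), cholangiocyte (Spp1 1.02, Sox9 -0.29) and exocrine pancreas (Cela1 0.71, Cela2a 1.60) genes were not called. No neutrophil or muscle marker passed the filter.

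**Figure D4:**
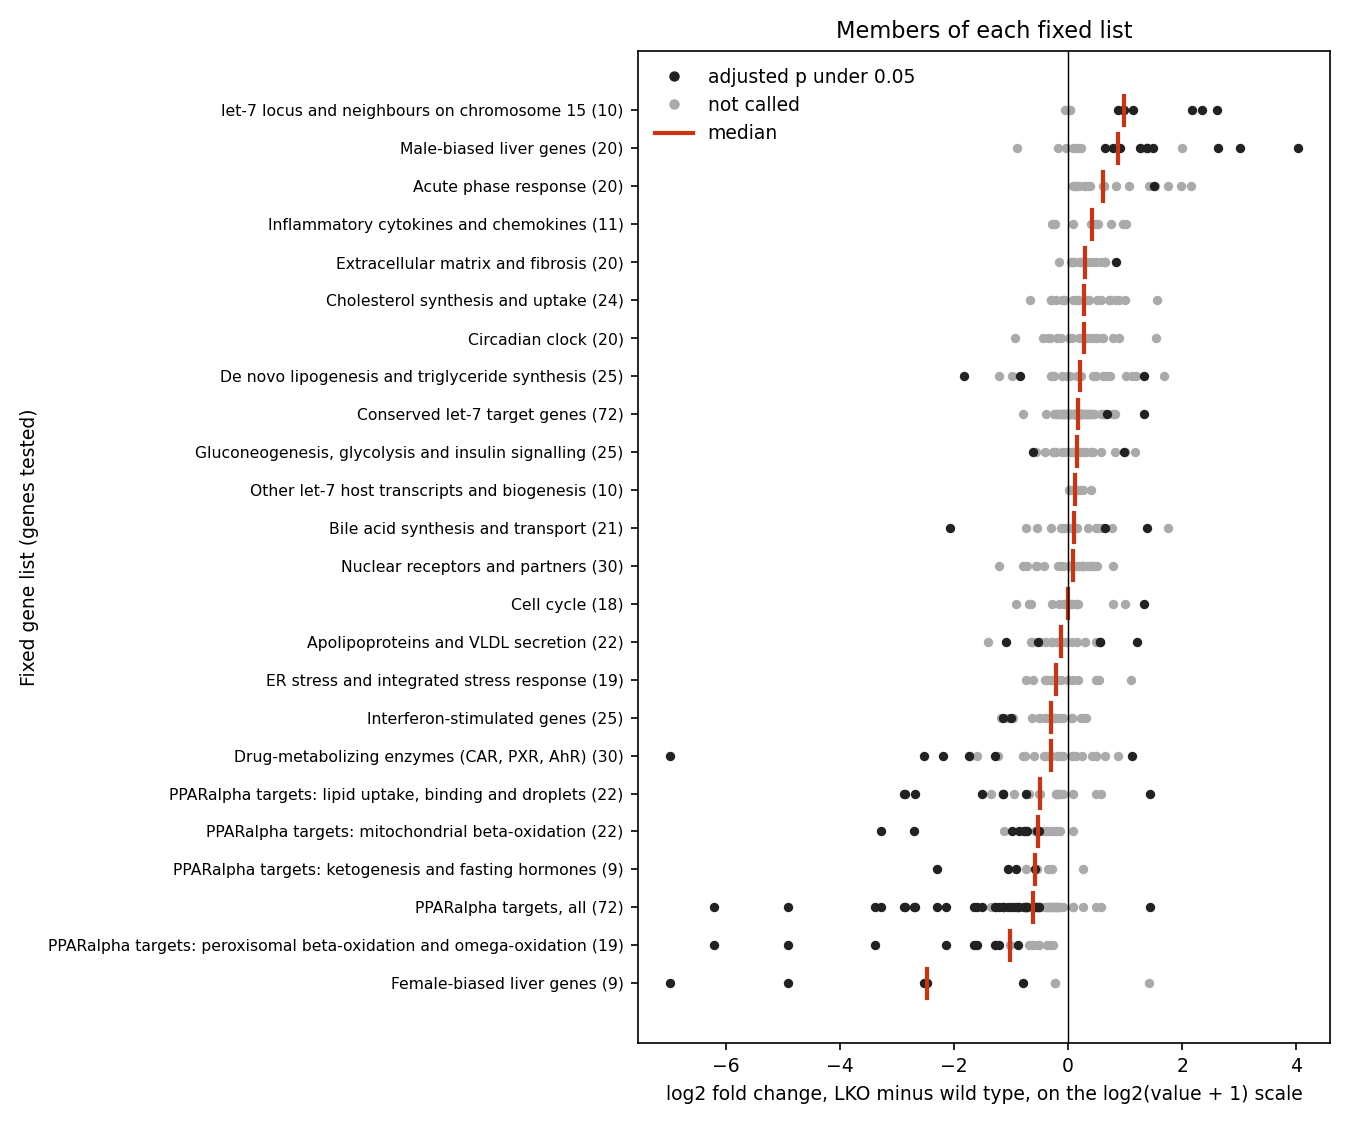
Log2 fold change (LKO minus wild type) of each tested member of the 24 fixed lists, with called genes in black, others in grey and the median as a red line. The medians run from -2.47 for female-biased genes, or -0.24 over 13 members without the filter on low values, to 0.97 for the neighbours of the let-7 locus.

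Of the 24 list tests, 14 were called with the preset correlation, 6 up and 8 down. None was called with an estimated correlation, and 11 were called by fry, which left out the cholesterol, interferon, acute phase and extracellular matrix lists and added that of inflammatory cytokines. Other groupings of the same 6 libraries, in which the genotypes are unevenly mixed, gave between 4 and 15 calls with the preset correlation. The number of lists called did not stand above them. Part of the genotype difference stays in such groupings, so they do not show how many calls arise without it.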

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

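The pseudocount of 0.1, limma-voom and the stricter filter were added for the list results after seeing the data, as were the 2 reduced sex-biased lists and all alternatives for marker lists. All other alternatives were chosen before. The edgeR quasi-likelihood and DESeq2 fits planned before the data were examined were not run. The deposited values were scaled by 1 factor per library, and the counts recovered from them held fractions. The plan allowed for RSEM expected counts, so such fits stayed possible on the recovered counts, where only limma-voom was run. Raised and lowered counts stayed within 1.5 times the reported 203 and 189 with each scaling, filter, pseudocount and voom fit, at 154 to 207 and 158 to 205. Leaving out 1 library gave 76 to 277 raised and 79 to 263 lowered genes, and the cause was not tested beyond the smaller number of samples. Of 63 called genes named, 33 kept their call with each of the 6 libraries left out in turn and 32 in every alternative. None changed sign. The numbers that lost their call were 28 without wild type replicate 2, 24 and 22 without LKO replicates 3 and 2, 18 and 15 without wild type replicates 3 and 1, and 4 without LKO replicate 1. Camera run with an estimated correlation ended all list calls (14 to 0), with unchanged medians for PPARα targets (-0.62) and conserved let-7 targets (0.17). Their adjusted p, 0.167 for both, ranged down to 1.4e-26 and 2.4e-04 over the other alternatives. The estimates were 0.275 and 0.0232 against the preset 0.01. The list of the let-7 locus had an estimate of 0.0077, below the preset, and lost its call too. Its unadjusted camera p went from 3.1e-08 to 0.0050, so for that list a larger correlation was not the cause. With an estimated correlation camera takes its degrees of freedom from the 6 libraries, and with a preset one from the genes. At a like correlation this by itself gives larger p-values. The lost calls thus do not measure correlation between genes. Over the left-out libraries the medians ran from -0.68 to -0.53 and from 0.14 to 0.22, and list calls from 13 to 17. The let-7 8mer difference ran from 0.02 to 0.08 and passed in no alternative tested with camera. In a regression across genes, which are not independent, it was 0.046 (p 0.036) alone and 0.026 (p 0.242) with untranslated region length and GC content.

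The replicate numbers did not pair the samples. Deviations of same-numbered libraries correlated at 0.0465, 0.0324 and 0.0535, all under 0.1, although each library correlated best with its own number, a hint from the data rather than the design. With the replicate block 217 genes were raised and 199 lowered, and 15 lists were called, with the inflammatory cytokine list (adjusted p 0.025) added, and 7 of the 8 genes beside the let-7 locus.

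Signs changed only for values that were not called. With library size alone, log2 fold changes became -0.040 for Ppara, -0.061 for Rxra, -0.026 for Nup50, -0.055 for Ddx3y, -0.040 for Alb and -0.027 for Dcn, a scaling that moved the median of all genes from -0.0017 to -0.065. The cell cycle list, tested up at a median of -0.0085, was tested down with voom (-0.023), the smaller pseudocount (-0.014) and the block (-0.0085). Over left-out libraries the ranges that crossed 0 were -0.050 to 0.13 for Ppara, -0.033 to 0.05 for Rxra, -0.15 to 0.032 for Atxn10, -0.050 to 0.10 for Nup50, -0.091 to 0.28 for Sc5d, -0.13 to 0.58 for Tef, -0.098 to 0.12 for Ddx3y, -0.21 to 0.19 for Alb, -0.42 to 0.99 for Ighm, -0.037 to 0.11 for Dcn, -0.64 to 0.052 for Sox9, -0.33 to 0.035 for Fabp4, -0.17 to 0.14 for the cell cycle list, -0.26 to 0.028 for ER stress and -0.052 to 0.10 for stellate markers. The cause was not tested. Depth limits genes near 3 reads, and 3 libraries per group recovered 19.3% of simulated 1.5-fold changes.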

Other observations

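The comparisons with other splits of the libraries were fixed before these results were seen for the number of lists called, PPARα targets, conserved let-7 targets and the let-7 8mer. All other tests in this part were chosen afterwards, those of sex-biased lists and gene counts over the other splits included. Gene families were grouped by name after the values were seen, in 15 families tested with camera and adjusted together. They were not fixed lists, but some hold members of those lists. Of 24 tested complement genes 8 rose and none fell, with a median log2 fold change of 0.54, an adjusted p of 4.0e-09 and an adjusted p = 0.167 with an estimated correlation. They included the terminal components C8b (1.48), C9 (1.05) and Hc (0.72), while C6 and C8a are also on the male-biased list and C1qc is a macrophage marker. Of 19 tested Mup genes 11 rose and none fell (median 1.78, adjusted p 7.9e-14, and adjusted p = 0.167 with an estimated correlation). Some of them, Mup1 and Mup7 included, are on the male-biased list, so this result partly repeats that one. Both metallothionein genes rose, Mt1 by 2.53 and Mt2 by 2.88. Of 14 carboxylesterase genes 6 fell, among them Ces1d (-1.55) and Ces1f (-1.36), and 2 rose, Ces4a (1.76) and Ces3b (1.11), and the family was not called (adjusted p 0.0772). The directions of these medians were the same with median-of-ratios factors and library size alone. Close copies share reads in the Mup and carboxylesterase families. Of 75 oxidative phosphorylation genes 1 fell, Ndufb6 (-0.55), and 68 values were negative, with a median of -0.16. The camera adjusted p was 2.1e-05, and 0.529 with an estimated correlation. Of 37 proteasome subunit genes 33 values were negative, with a median of -0.13. Their camera adjusted p was 0.0040, and 0.529 with an estimated correlation. The 12 mitochondrially encoded transcripts of the same livers had a median of -0.33.

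The first pattern is the rise of 8 neighbouring genes beside the let-7 locus. In 1000 permutations of gene positions at most 5 raised genes fell in 8 consecutive ones (p = 0.001, the smallest they can give). The same scan found 7 raised of 8 at a Mup cluster on chromosome 4. It also found 5 lowered Ces1 genes of 8 on chromosome 8, against a permuted maximum of 4 (permutation p = 0.001). Permuted positions ignore such clusters of related genes, so this p does not set the let-7 locus apart from them. For 7 of the 8 genes beside the let-7 locus, loss of repression at let-7 sites is argued against. Of their annotated 3′ untranslated regions, 0 hold a 7mer or 8mer site. Tbc1d22a holds 1 such site, as do 17.1% of all tested genes with an untranslated region, which leaves this open for that gene. Strain variants carried with the edited allele and an effect of the allele on its neighbours cannot be told apart, because each LKO mouse has both the allele and its flanks. Of the 4 tested genes as far upstream 0 were called, too few to decide, and the fold had a Spearman rho of -0.643 with distance across the 8 genes (exact permutation p = 0.0962, two-sided), so either may be the source.

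The second pattern is the rise of male-biased and fall of female-biased genes, whose median of -2.47 was -0.24 without the filter on low values. Libraries of different sex are argued against by Ddx3y, which lay at 29.9 or above in all 6 libraries, and by Xist, listed at 0 in each. Reads shared between Mup copies cannot carry the rise, as the 15 male-biased genes without Mup members had a median of 0.91. Of the 9 tested female-biased genes only Acot3 was shared with the PPARα lists, so leaving it out tested little. The other 8 had a median of -1.63, which this overlap does not account for. Some of these passed the filter through their wild type values, such as Hao2 with means of 4.56 and 0 in LKO. The shorter list was not run without the filter, so the overlap stays open there. An effect of the knockout, or of a hormonal difference between the mice, may be the source and stays untested.

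The third pattern is the fall of PPARα targets. A fall of the Ppara transcript of the same size is argued against by the lower end of its 95% interval, -0.25, which lies above the list median of -0.62. A lower share of hepatocytes would lower hepatocyte markers by as much, but the intervals of 7 of 10 lay above that median. The authors' scaling of the libraries is argued against by the list median, which was -0.69 with library size alone and -0.62 with median-of-ratios factors in its place. Lower activity of the receptor, whose transcript was not called (95% interval -0.25 to 0.31), may be a source, as a hypothesis. So may a difference in feeding or fasting state between the mice. Neither was tested.

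Other groupings of the 6 libraries were compared with the real one. There are 10 ways to split them 3 against 3, too few for a share under 0.1. Each other split holds an uneven mix of genotypes. Part of the genotype difference stays between its groups, and part adds to the spread within them. The other splits thus do not show what would be called with no genotype difference. The real split called 203 raised and 189 lowered genes, and the highest count in the others was 0. For lists called, the real count was 14 and the highest other 15, so 2 of the 10 splits, the real one included, gave as many. The real medians were -0.62 for PPARα targets, 0.173 for conserved let-7 targets, 0.882 for male-biased and -2.47 for female-biased genes. The highest absolute medians in the other splits were 0.399, 0.123, 0.546 and 0.904, in the same order, and for the let-7 8mer difference the real and highest other values were 0.0525 and 0.0494.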
